A study of Neurospora crassa with 94 samples.

How the data were processed

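The series profiled Neurospora crassa, a filamentous fungus, grown as mycelial cultures in constant light, per the labels. Of 94 samples, 41 were RNA-seq libraries and were analysed; the other 53, from ChIP-seq and MNase-seq, were not analysed here. The RNA libraries fell into 14 groups of genotype and library series, and the series are named here by the number that opens each library's label. Series 111 held wild type (WT), acf, iaf-1 and iaf-2, with 3 libraries each. Series 112 held WT, set-7, acf and the acf iaf-1 iaf-2 triple mutant, with 3 libraries each. Series 118 held WT, isw, acf iaf-1, acf iaf-2 and acf iaf-1 iaf-2, with 3 libraries each, and iaf-1 iaf-2 with 2. Nothing in the labels states that replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

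RNA was prepared with Trizol and lithium chloride and made into libraries with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name Trim Galore 0.4.4, cutadapt 1.14, FastQC, HISAT2 2.1.0, SAMtools 1.9 and featureCounts of Subread 1.6.2, without settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes on opposite strands, and reads shared by near-identical copies such as the histone H4 genes, are therefore uncertain, and no coordinates are printed. The authors deposited whole-number read counts per gene for series 111 and 112, and TPM (reads scaled for gene length and library total) for series 118. No column of the tables was left without a sample. Of 10397 gene identifiers, 10363 matched a locus tag of the RefSeq table for assembly NC12, used only for symbols and gene order, and 34 did not.

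The design written before the data were examined assumed counts in all series. Since series 118 held TPM, its comparisons were tested on log2(TPM + 1) with limma, and its fold changes are on that scale, which understates changes of genes with low values. TPM values of each gene were whole multiples of a common step within a tolerance of 0.001, which gave whole reads for 10397 genes, or 100%. Library totals from these recovered reads, CPM (reads scaled to the library total) of series 118 and an edgeR test as an alternative rest on them. A gene with no read in a group was set at a floor of 3 reads over the group's summed libraries, and ratios with 1 to 3 reads on one side carry an exact 95% counting interval. Floors and intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

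Each mutant was compared with WT of its own series, and all groups of the series entered the fit. Counts were tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, robust dispersion). TPM were tested with limma (trend and robust options) over genes of at least 1 TPM in at least 2 libraries. For acf, present in series 111 and 112, edgeR was fitted over both with a series term, and for the triple mutant, present in series 112 and 118, limma was fitted over both with the counts converted to TPM. A genotype by series interaction tested whether an effect differed between series. Calls used Benjamini-Hochberg adjusted p with a threshold of 0.05 over all genes tested. The named genes followed a rule fixed with the design. It takes the deleted genes, then the 8 highest and 8 lowest fold changes (4 and 4 for the smaller comparisons) among called genes changed at least 2-fold. Such genes needed a mean of at least 5 in the higher group, in CPM or, for series 118, in TPM. In fits over both series this mean was averaged over the series, so a gene could lie below 5 in one. Every mutant library also had to lie on the same side of every WT library of its series. The rule adds up to 4 called members of each gene list in the set-7, isw, acf and triple mutant comparisons.

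A total of 9 gene lists were fixed with the design: Polycomb and ASH1 machinery, ISWI complex, heterochromatin and DNA methylation, histones, conidiation, sexual development, light response and clock, cellulose utilization, and heat shock and oxidative stress. The first of these is named after ASH1 too, but its 4 genes include no ASH1 gene. Another 8 lists, built from the symbols in the reference table, were added once the tables had been seen: glycoside hydrolases, respiratory complex I, vacuolar ATPase, proteasome, kinases, DNA repair, amino acid synthesis and peroxisome. They were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. Adjusted p for lists is over the fixed or the added lists of one comparison. Genes called higher at least 2-fold in set-7 formed the set-7 list, tested the same way in the 8 mutants set against WT of series 111 or 118 and adjusted over these 8. The share of genes called higher at least 2-fold among the 50 genes at each chromosome end was compared with other genes by Fisher's exact test (two-sided). The calls were then rotated along the gene order 10000 times, since neighbouring genes are not independent.

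Replicates were compared before averaging, by a chi-square of their counts over genes. In each group of series 111, 1 pair of libraries differed far less than the others, and counts of changed genes, named genes, list tests and the tests of patterns in series 111 were repeated with that pair summed and counted as 1 sample. The text gives the named genes that lost their call in acf over both series and in iaf-2. Counts over other splits were so repeated only for acf over both series. The list tests of acf over both series and rotations along chromosomes were not repeated, nor was fry, a further list test of limma used on the set-7 list. Alternatives were other scaling (size factors of DESeq2 in edgeR, median-ratio scaling of TPM), no filter, DESeq2, only the compared groups, all RNA libraries in one fit, the replicate number as a block, each library left out, and other list and end sizes. Pseudocounts of 0.25 and 4, edgeR on recovered reads and the summed pairs were added after the data were seen. Tests were run first on simulated counts with 200 changed genes. For set-7 against WT, edgeR recovered 34.3%, 73.1% and 89.4% of genes changed 1.5-, 2- and 4-fold among 8145 genes. For isw against WT, limma recovered 28.4%, 82.1% and 93.9% among 8221 genes. For acf over both series the shares were 13.4%, 70.1% and 97.0% among 8028 genes, and for the triple mutant over both series 41.8%, 83.6% and 95.5% among 8230 genes. Unchanged genes made up 11.5% of the simulated calls for set-7 (13.1% with DESeq2), above the threshold of 0.05, 4.9% for isw, 4% for acf and 6.4% for the triple mutant. The simulation changed far fewer genes than the real fits called. It also drew all libraries as independent, without the near-identical pairs of series 111. A low simulated share thus says little about the real calls, least of all those of acf. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.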

Results

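RNA-seq of Neurospora crassa measured the expression of 10397 genes in 41 libraries, prepared in 3 library series. The strains were wild type (WT) and deletions of set-7, of isw (symbol crf4-1 in the reference), of acf (crf4-2), of iaf-1 (NCU00412), of iaf-2 (NCU09388) and of combinations of the last 3. Each group held 3 libraries, except the iaf-1 iaf-2 double mutant with 2. Library totals lay between 5332503 and 9021398 reads in series 111, between 5652592 and 22582163 in series 112 and between 11711993 and 21973650 in series 118. The 10 most abundant genes took 8.89% to 12.05% of reads in series 111, 14.97% to 17.93% in series 112 and 13.76% to 17.44% in series 118. In series 111, 1 pair of libraries in each group was nearly identical: the chi-square per degree of freedom was 1.93 for WT replicates 1 and 3, 1.80 for acf replicates 1 and 2, 1.53 for iaf-1 replicates 1 and 3 and 1.63 for iaf-2 replicates 1 and 2, where counting noise alone gives about 1. The other pairs in all series lay between 6.93 and 127, so the counts of changed genes, the called lists and the set-7 list of series 111 are also given with each pair summed.

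The deleted genes were read first in every library. NCU00412 had no read in the 3 iaf-1 libraries against 49.7 CPM ± 7.62 (SD, n = 3) in WT, at least 345-fold lower over a floor of 3 reads in the group. NCU09388 had 2 reads in iaf-2 against 1091 in WT, a ratio of 0.00155 (95% counting interval 0.000188 to 0.00562). The isw gene, which encodes the ATPase of ISWI chromatin remodelers, stood at 2.12 TPM ± 0.445 in isw against 33 ± 3.34 in WT (SD, n = 3), 10.9-fold lower (limma adjusted p = 8.46e-13). Reads of the set-7 gene were still present in the libraries labelled set-7, at 4.42 CPM ± 0.492 against 7.29 ± 1.58 (SD, n = 3; edgeR log2 fold change -0.65 ± 0.20 SE, adjusted p = 0.0423); this call was lost without WT replicate 1 or 2 or any 1 set-7 replicate (log2 fold change -0.73 to -0.49), without the filter and with only the compared groups in the fit. Reads of the acf gene went against the label: they were higher, not lower, in the libraries labelled acf, at a mean of 188 CPM against 43.1 in series 111 and of 74.3 against 30.1 in series 112 (n = 3 each; edgeR over both series, log2 fold change 1.86 ± 0.21 SE, adjusted p = 4.97e-05; 0.000403 with close pairs summed). The acf gene was also higher in the libraries labelled acf iaf-1 (1.65-fold, limma adjusted p = 0.000689), acf iaf-2 (1.61-fold, 0.00107) and acf iaf-1 iaf-2 (1.86-fold, 3.74e-05). Which part of the set-7 and acf genes was removed is not given in the sources used here, so reads outside the removed part cannot be told from reads of an intact gene, and both genotypes rest on the labels. In the combined mutants the iaf genes were low: NCU00412 had 12 reads in acf iaf-1 and 23 in iaf-1 iaf-2, and NCU09388 had 5 in acf iaf-2 and 15 in iaf-1 iaf-2. The triple mutant had 40 reads of NCU00412 and 34 of NCU09388 in series 112, of which 1 library held 35 and 26, and 5 and 18 in series 118.

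SET-7 is the catalytic subunit of PRC2, which methylates histone H3. The libraries labelled set-7 were compared with WT to ask which genes its loss would release. Genes near the ends of chromosomes V and IV stood out in the libraries labelled set-7. NCU07147 averaged 63.2 CPM ± 4.13 (SD, n = 3) against no read in WT, at least 603-fold higher, and its neighbours NCU07150 and NCU07148 were at least 505-fold and 109-fold higher. Counted from the nearest end of chromosome V these were genes 5, 8 and 6, and NCU07152 and NCU07144 were genes 10 and 2. NCU07152 had 591 reads against 1 (ratio 403, counting interval 72.0 to 15900), and NCU07144 stood at 13.8 CPM ± 4.33 against 0.122 ± 0.127 (SD, n = 3; edgeR adjusted p = 2e-06). NCU10037, the outermost gene of chromosome IV, was 49.2-fold higher (edgeR adjusted p = 9e-06), and NCU05173, gene 23 from an end of IV, had 633 reads against 2 (216, 59.5 to 1790). NCU07249, gene 111 on chromosome V, had 1233 reads against 2 (420, 116 to 3470). At the other extreme, NCU09968 and NCU09969, neighbours on chromosome VI, had no read against 90.8 CPM ± 16.1 and 12.6 ± 2.84 in WT (SD, n = 3), at least 1270-fold and 177-fold lower. Both also had few or no reads in acf, iaf-1, acf iaf-1, acf iaf-2 and the triple mutant. In iaf-2, isw and iaf-1 iaf-2, NCU09968 stood at 59.5, 41.5 and 39 CPM. Here and below, a loss of these neighbours thus cannot be told from a difference in strain. NCU02022 was 10.3-fold lower, NCU01957 8.72-fold, NCU02061 8.36-fold, NCU02071 5.05-fold and NCU02051 3.62-fold, all on chromosome I, and NCU01209 on chromosome V was 3.46-fold lower (edgeR adjusted p between 3.41e-07 and 0.000261 for these).

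Among the fixed lists, the light response and clock list fell in the libraries labelled set-7 (camera adjusted p = 0.0339; adjusted p = 0.569 with an estimated correlation). Of its 11 measured members 2 fell, and 2 when adjusted over the list alone. They were wc-2, a subunit of the White Collar photoreceptor complex, at 52.4 CPM ± 7.45 against 86.1 ± 10.9 (SD, n = 3; edgeR adjusted p = 0.00144), and cry, a cryptochrome, at 85.7 ± 12.5 against 120 ± 4.26 (0.0331, lost without any 1 WT library or without set-7 replicate 2 or 3, at log2 fold changes of -0.44 to -0.28). The conidiation gene con-6 was 3.62-fold higher (edgeR adjusted p = 0.0124, log2 fold change 1.41 and no longer called without WT replicate 2). Neither con-6 nor cry was called with only WT and set-7 in the fit. The mating-type gene matA-1 had no read against 1.81 CPM ± 1.34 in WT (SD, n = 3), at least 25.3-fold lower. It had at most 3 reads in every mutant group but acf iaf-1. Here and below, its loss thus cannot be told from a difference in strain or mating type between mutant and WT. In total 1235 of 8747 genes changed (edgeR), 647 higher and 588 lower, and at least 2-fold changes numbered 263 higher and 69 lower. In a simulation of this comparison the false share of calls lay above the threshold of 0.05. Without WT replicate 3 the majority turned, with 776 higher and 809 lower. The total was 447 with only WT and set-7 in the fit, and 741 without WT replicate 2.

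The isw comparison asked what the loss of the ISWI ATPase changes. The pheromone gene mfa-1 and several genes that were nearly silent in WT rose to high levels. mfa-1, the precursor of the mating pheromone made by mat a strains, stood at 31000 TPM ± 3630 in isw against 22.1 ± 8.03 in WT (SD, n = 3; limma log2 fold change 10.44 ± 0.51 SE on the log2(TPM + 1) scale, adjusted p = 7.7e-10). pre-2, a pheromone receptor gene, was 102-fold higher (limma adjusted p = 9.92e-15) at 275 TPM ± 25.4 against 1.71 ± 0.426, and per-1, needed for black perithecia, was 14.6-fold higher (limma adjusted p = 2.43e-12) at 16.4 TPM ± 1.84 against 0.19 ± 0.0681. NCU10502 stood at 5970 TPM ± 373 against 2.12 ± 2.38, NCU16929 at 5180 ± 882 (limma log2 fold change 10.75 ± 0.27 SE) and NCU04869 at 1790 ± 48.6 against 0.245 ± 0.424 (SD, n = 3). NCU04867 stood at 595 TPM ± 36 against 0.171 ± 0.296 and NCU04860 at 470 ± 21.8 against 0.197 ± 0.25. NCU10644 had 9964 reads against 3 (ratio 3070, counting interval 1050 to 14900) and NCU09952 had 6872 against 2 (3170, 878 to 26200). NCU10502, NCU10644, NCU04869, NCU04867 and NCU04860 lay on chromosome IV as genes 145, 144, 135, 134 and 129 from the nearest end. The genes that fell furthest were NCU00995, at 10.1 TPM ± 4.12 against 1070 ± 131 (SD, n = 3; 99.6-fold, limma adjusted p = 1.15e-13), NCU09209 (24.6-fold), NCU06305 (23.1-fold), NCU05068 (19.6-fold), NCU09906 (16.8-fold), NCU01735 (15.1-fold), NCU09904 (log2 fold change -3.89) and NCU05070 (13.2-fold).

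**Figure D1:**
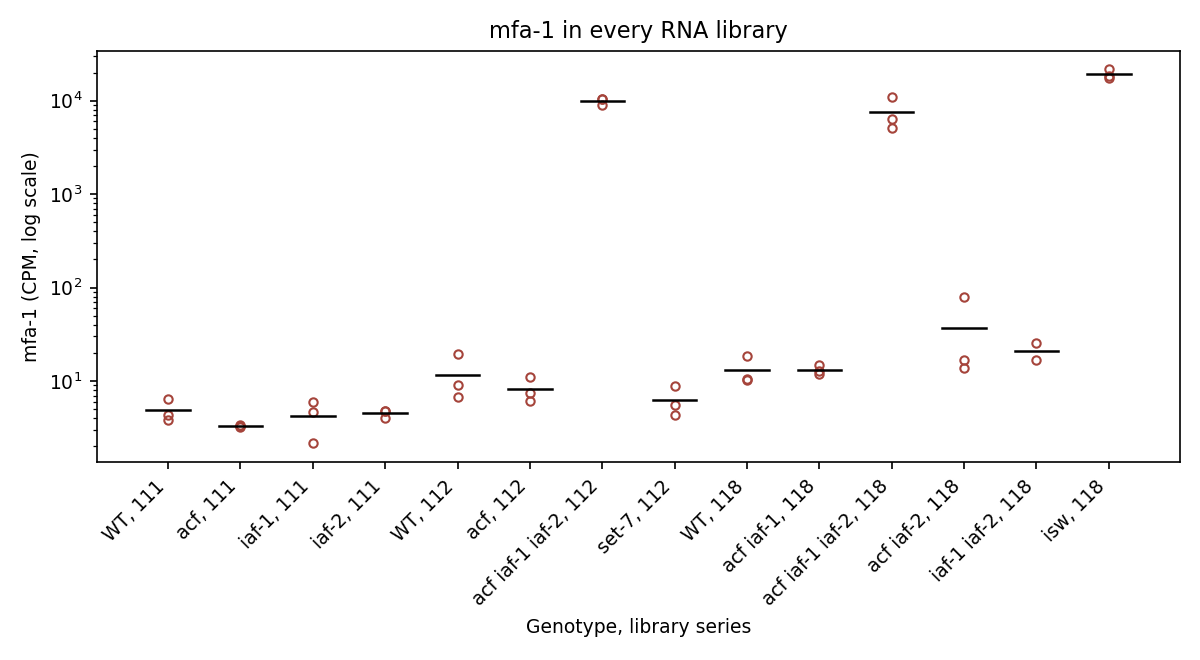
Reads of mfa-1 as CPM on a log scale (vertical axis) in each of 41 libraries (points), by group (horizontal axis), with a bar at each group's mean. The isw libraries and the acf iaf-1 iaf-2 libraries of both series lie at 5090 CPM or above.

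Light-regulated genes fell in isw. Of 11 members 8 fell and 1 rose, and 9 changed when adjusted over the list alone (camera adjusted p = 0.00135; adjusted p = 0.37 with an estimated correlation). The carotenoid genes al-1 and al-2 fell 3.43-fold and 2.3-fold, bli-3 fell 3.09-fold to 442 TPM ± 102 from 1350 ± 183 (SD, n = 3) and cry fell 2.13-fold (limma adjusted p between 2.71e-08 and 7.15e-06). In the sexual development list 3 of 7 members rose and 1 fell, 4 adjusted over the list alone (camera adjusted p = 0.326). In the conidiation list 2 of 9 rose and 4 fell, 6 adjusted over the list alone (0.663): con-6 rose 13.1-fold, and csp-1, ccg-1 and the regulator fl fell 1.98-fold, 2.68-fold and 1.53-fold. Of the Polycomb and ASH1 list, whose 4 members include no ASH1 gene, 3 rose and 1 fell, 4 adjusted over the list alone (camera adjusted p = 0.438). Its members NCU05300 (EED of PRC2), set-7 and NCU07505 (epr-1) rose 2.53-fold, 1.69-fold and 1.72-fold, and NCU05460 (SUZ12) fell 1.57-fold. The ISWI complex list includes the deleted gene, and 3 of 4 members rose and 1 fell, 4 adjusted over the list alone (0.682); the acf gene rose 2.78-fold (limma adjusted p = 1.11e-07). Of 6 heterochromatin and DNA methylation genes 3 rose, 3 adjusted over the list alone (0.344), among them dim-5, a histone H3 methyltransferase, 1.6-fold. Of 7 histone genes hH3, hH4-2 and hH2Az rose 1.38-fold, 1.37-fold and 1.25-fold, and 3 passed adjusted over the list alone (0.326). In the cellulose list 3 of 10 rose and 1 fell, 4 adjusted over the list alone (0.682), with the cellulase gene gh5-1 5.65-fold higher and the regulator clr-2 1.85-fold higher, and gh61-4 at 2.76 TPM ± 0.97 against 0.141 ± 0.244 (SD, n = 3). Of 9 heat shock and oxidative stress genes 4 fell, 4 adjusted over the list alone (0.227), among them hsp30 1.74-fold and the catalase genes cat-3 and cat-2 1.78-fold and 1.97-fold.

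Among the added lists, respiratory complex I fell in isw, with 19 of 29 members lower (camera adjusted p = 4.63e-05; adjusted p = 0.239 with an estimated correlation). Amino acid synthesis had 20 of 53 members lower and 2 higher (0.000215; adjusted p = 0.941 with an estimated correlation), and the vacuolar ATPase had 6 of 13 lower (0.0175; adjusted p = 0.94 with an estimated correlation). Glycoside hydrolases had 29 of 75 higher and 11 lower (0.322), DNA repair 15 of 30 higher and 2 lower (0.322), kinases 14 of 66 higher and 10 lower (0.994), the proteasome 2 of 17 higher (0.994), and the peroxisome 2 of 20 higher and 1 lower (0.944). Over all comparisons and both sets of lists, 51 of 255 list results were called, and 2 of them held with an estimated correlation: complex I in the triple mutant and sexual development in acf iaf-1. The latter includes matA-1 and ccg-4, whose rise cannot be told from a difference in strain or mating type. In total 4513 of 9339 genes changed in isw (limma), 2708 higher and 1805 lower, with 1338 higher and 458 lower at least 2-fold.

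The triple mutant, labelled as lacking ACF and the accessory factors IAF-1 and IAF-2, was compared with WT over series 112 and 118. Here too mfa-1 and genes with few reads in WT led. mfa-1 stood at 9970 CPM ± 820 against 11.7 ± 6.68 in series 112 and at 12500 TPM ± 5200 against 22.1 ± 8.03 in series 118 (SD, n = 3; limma log2 fold change 9.40 ± 0.27 SE, adjusted p = 1.06e-11). pre-2 and per-1 were 118-fold and 24.1-fold higher (limma adjusted p = 7.49e-13 and 7.08e-12). NCU10502 stood at 1460 CPM ± 76.4 against 0.745 ± 1.18 and 3860 TPM ± 263 against 2.12 ± 2.38, and NCU08969 at 502 CPM ± 60.1 against 0.857 ± 0.418 and 954 TPM ± 218 against 1.06 ± 0.195 (SD, n = 3). NCU04869, NCU16929 and NCU04860 were 1010-fold, 600-fold and 435-fold higher, NCU04867 had 10907 reads against 1 in series 112 (ratio 7840, counting interval 1410 to 310000), and NCU10644 had 6179 against 3 in series 118 (2080, 713 to 10100). The genes that fell furthest were NCU00995 (46.3-fold), NCU09209 (16.2-fold), NCU10040 (15.3-fold), NCU09906 (14.3-fold) and NCU08720 (10.7-fold), with NCU07736 and NCU05639 at log2 fold changes of -3.62 and -3.54. NCU09968 had no read in series 118, at least 1080-fold lower, and 0.906 CPM ± 1.15 against 90.8 ± 16.1 in series 112 (SD, n = 3); DESeq2 did not call it.

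Light genes fell as a list in the triple mutant: 10 of 11 fell and 1 rose, 11 adjusted over the list alone (camera adjusted p = 0.000188; adjusted p = 0.209 with an estimated correlation). The photoreceptor gene vvd fell 3.63-fold, bli-4 5.37-fold, al-1 3.93-fold and cry 3.1-fold (limma adjusted p between 2.35e-09 and 2.86e-06). Respiratory complex I fell, with 24 of 29 members lower (camera adjusted p = 4.69e-07; adjusted p = 0.036 with an estimated correlation, but 0.938 in series 112 and 0.0944 in series 118 alone). Amino acid synthesis had 25 of 53 lower and 2 higher (camera adjusted p = 0.00107, and 0.779 with an estimated correlation) and the vacuolar ATPase 7 of 13 lower (0.0135, and 0.302 with an estimated correlation). Neither list was called in series 112 alone (camera adjusted p = 0.448 and 0.556), while both were in series 118 (4.92e-05 and 0.00435). con-6 and eas, the gene of the hydrophobin coating conidia, were 11.2-fold and 7.69-fold higher, and con-8 and ccg-1 were 1.94-fold and 1.87-fold lower. gh5-1 and clr-2 were 6.6-fold and 1.81-fold higher, while hsp30, sod-1 (a superoxide dismutase gene) and cat-2 were 2.04-fold, 1.86-fold and 2.69-fold lower. hH3 was 1.36-fold higher and hH2A 1.44-fold lower. set-7 and NCU05300 were 1.62-fold and 1.89-fold higher, and NCU05460 was 1.98-fold lower. In total 5008 of 9294 genes changed (limma), 2427 higher and 2581 lower, with 4805 in series 112 (edgeR) and 4768 in series 118 (limma). Which direction held the majority turned with the method: 2828 were higher and 2187 lower with median-ratio scaling, 3004 and 2284 with DESeq2 and 2601 and 2233 with edgeR on recovered reads. Fold changes of the 2 series, across 8719 genes that are not independent and with different WT libraries, had Pearson's r of 0.81 and Spearman's rho of 0.63.

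Within series the triple mutant was set directly against acf and against isw. Against the libraries labelled acf (series 112), light genes fell, 8 of 11 members (camera adjusted p = 0.0137; adjusted p = 0.181 with an estimated correlation), as did complex I, 18 of 29 (2.34e-06; adjusted p = 0.576 with an estimated correlation), and amino acid synthesis, 19 of 53 with 3 higher (0.00812; adjusted p = 0.766 with an estimated correlation). In that comparison 4214 genes changed (edgeR), 2183 higher and 2031 lower, 946 and 478 of them at least 2-fold. Against isw (series 118), 1634 genes changed (limma), 796 higher and 838 lower, and 73 and 113 at least 2-fold. The majority turned here too, with 991 higher and 910 lower with median-ratio scaling, 1182 and 991 with DESeq2 and 1107 and 801 with edgeR on recovered reads. The total was 846, 985 and 1056 without isw replicate 1, 2 or 3 and 951 without triple mutant replicate 2. The ISWI complex list, which holds the deleted genes of both strains, had 1 member higher and 3 lower (camera adjusted p = 0.0223; adjusted p = 0.422 with an estimated correlation). Glycoside hydrolases had 12 of 75 higher and 1 lower and complex I 2 of 29 lower (camera adjusted p = 0.0254 each; adjusted p = 0.912 with an estimated correlation).

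ACF is a partner subunit of ISWI chromatin remodelers, and the libraries labelled acf were compared with WT over series 111 and 112. Genes with almost no reads in WT rose in the libraries labelled acf. NCU04703 stood at 8.27 CPM ± 2.45 in series 111 and 11.0 ± 0.0537 in series 112 against no read in WT (SD, n = 3), at least 58.2-fold and 104-fold higher, and NCU12045 was at least 45.1-fold and 93.7-fold higher. NCU07091 had 443 reads against 2 (ratio 226, counting interval 62.2 to 1870) and 1473 against 2 (426, 118 to 3520). NCU09605, NCU08222 and NCU08863 were at least 117-fold (series 112), 66.1-fold (series 111) and 107-fold (series 112) higher. NCU07087 and NCU09589 were at least 43.2-fold (series 112) and 12.4-fold (series 111) higher. gh5-1 was 19.6-fold higher (edgeR adjusted p = 2.91e-07) and its regulator clr-2 3.21-fold. eas stood at 643 CPM ± 23.9 against 37.6 ± 35.5 and at 93.9 ± 43.1 against 18.2 ± 12.8 (SD, n = 3; edgeR adjusted p = 0.00163), while con-10 was 2.57-fold lower. phr, the gene of a light-driven DNA repair enzyme, was 3.61-fold lower (edgeR adjusted p = 6.78e-06) and cat-2 2.28-fold lower. NCU09968 and NCU09969 had no read in the libraries labelled acf, at least 820-fold and 55-fold lower in series 111 and 1500-fold and 208-fold in series 112. matA-1 was at least 120-fold lower in series 111. NCU00995 was 9.13-fold lower, NCU03646 6.17-fold and NCU02022 5.72-fold (edgeR adjusted p between 4.45e-07 and 2.3e-05). NCU02238 was 7.54-fold lower, with 10 reads against 350 in series 111 and 23 against 23 in series 112. app was 6.6-fold lower and was not called by DESeq2.

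The proteasome list fell in the libraries labelled acf over both series, with 10 of 17 members lower (camera adjusted p = 0.000646), DNA repair had 10 of 30 lower (0.00832), and amino acid synthesis had 24 of 53 higher and 3 lower (0.00112); each gave adjusted p = 0.525 with an estimated correlation. In series 111 alone the proteasome had 14 of 17 lower and 1 higher (camera adjusted p = 0.00172), DNA repair 17 of 30 lower and 5 higher (0.0155), kinases 35 of 60 higher and 10 lower (0.002) and amino acid synthesis 30 of 53 higher and 9 lower (0.000576), each with adjusted p = 0.43 with an estimated correlation. With close pairs summed these 4 calls held (0.00291, 0.0243, 0.00291 and 0.000948), and complex I was called too, with 5 of 29 lower (0.0409). In series 112 alone none of the lists called over both series was called: the proteasome had 1 of 17 lower (camera adjusted p = 0.0891), DNA repair 2 of 30 lower and 1 higher and amino acid synthesis 5 of 53 higher and 2 lower (0.115 each). There kinases had 19 of 65 lower and 6 higher, with a median log2 fold change of -0.23 but a mean of 0.02, and the peroxisome 4 of 20 lower (camera adjusted p = 0.0262 each; adjusted p = 0.541 with an estimated correlation). In total 2404 of 8252 genes changed (edgeR), 1106 higher and 1298 lower. With close pairs summed the total was 1111, of which 720 were higher and 391 lower, a higher share of 64.8% in place of 46.0% (54.4% with size factors of DESeq2 in edgeR and 55.4% in DESeq2); dim-2, hpo, hH2A, clr-1, cbh-1, con-6, hsp30, hsp88 and NCU09388 were called only without that summing (log2 fold changes of -0.64, -0.61, -0.36, -0.51, -0.93, 1.37, -0.58, -0.47 and -0.52, against -0.57, -0.54, -0.31, -0.40, -0.77, 1.54, -0.51, -0.38 and -0.45 with it). Without WT replicate 3 of series 111 it was 1592. The libraries labelled acf differed between series: 5265 of 7974 genes changed in series 111, 47.8% of them higher (4105 with close pairs summed, 50.6%; 51.3% in DESeq2), and 2381 of 8747 in series 112. The interaction called 3920 genes (3513 with close pairs summed), and fold changes of the 2 series over 7941 genes had Pearson's r of 0.45 and Spearman's rho of 0.09.

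Genes of amino acid synthesis rose in iaf-1, 31 of 53 members with 2 lower (camera adjusted p = 6.46e-10; adjusted p = 0.356 with an estimated correlation); with close pairs summed 15 rose (1.22e-09). NCU06555 stood at 41.1 CPM ± 9.55 against 2.52 ± 0.52 (SD, n = 3; 17.2-fold, edgeR adjusted p = 6.56e-07, 0.00159 with close pairs summed). NCU01011 was 30.6-fold, NCU07441 18.8-fold and NCU00250 12.5-fold higher (edgeR adjusted p with close pairs summed 0.0396, 0.0327 and 0.0476). NCU09968 had 2 reads in iaf-1 against 2528 in WT (ratio 0.000802, counting interval 9.71e-05 to 0.0029), NCU09969 had 2 against 165 (0.0123, 0.00148 to 0.0451), and matA-1 was at least 121-fold lower. NCU09909 was 11.2-fold lower. Kinases had 15 of 60 higher (camera adjusted p = 0.00366), DNA repair 4 of 30 lower and 1 higher and the peroxisome 6 of 20 higher (0.0264 each; these 3 had adjusted p = 0.444 with an estimated correlation). With close pairs summed the DNA repair and peroxisome calls ended (camera adjusted p = 0.0865 and 0.0601) and the kinase call held (0.000701). Complex I was then called lower (camera adjusted p = 0.0321), though no member was called. In total 2299 of 7974 genes changed (edgeR), 1265 higher and 1034 lower, and 476 did with close pairs summed, 331 higher and 145 lower.

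In iaf-2 a few genes other than the deleted one stood apart, among them matA-1, which was low in every mutant group but acf iaf-1. NCU14009 stood at 9.64 CPM ± 1.76 against 98.0 ± 15.1 (SD, n = 3; 10.3-fold lower, edgeR adjusted p = 1.8e-06, 0.00196 with close pairs summed), and matA-1 had 1 read against 368 (0.0023, counting interval 5.81e-05 to 0.0129). NCU14085 was 4.66-fold higher, NCU04667 5.12-fold, NCU07441 8.38-fold and NCU00250 6-fold, while pho-4, a phosphate permease gene, was 15.4-fold and NCU07894 6.67-fold lower. All 6 lost their call with close pairs summed (edgeR adjusted p between 0.115 and 0.16), while their log2 fold changes went from 2.22 to 2.16, 2.36 to 2.30, 3.07 to 3.21, 2.59 to 2.73, -3.95 to -3.54 and -2.74 to -2.38, with fewer samples behind them; NCU07441 lost it also without WT replicate 1 or iaf-2 replicate 3 (log2 fold changes 2.77 and 2.47), and NCU00250 also without WT replicate 1 or 3 or iaf-2 replicate 3 (2.35, 2.32 and 1.74). Of 7 histone genes 2 fell, 6 adjusted over the list alone (camera adjusted p = 0.0167; adjusted p = 0.504 with an estimated correlation), and the list call held with close pairs summed (0.0321), though no member was among the 4 genes then called. Kinases had 11 of 60 higher and 2 lower (0.029; adjusted p = 0.704 with an estimated correlation; 0.00592 with close pairs summed). In total 1564 of 7974 genes changed (edgeR), 808 higher and 756 lower, against 933 and 946 in DESeq2. With close pairs summed 4 did, all lower: NCU09388, matA-1, NCU14009 and NCU16306, the last named after its values were seen (adjusted p = 0.0435, 7.05 against 25.1 CPM), and 1466 had an unadjusted p under 0.05. It was 792 with only WT and iaf-2 in the fit, and 790, 2759 and 871 without WT replicate 1, 2 or 3 and 912, 951 and 769 without iaf-2 replicate 1, 2 or 3.

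Sexual development genes rose in the libraries labelled acf iaf-1, 5 of 7 members and 5 adjusted over the list alone (camera adjusted p = 0.00068; adjusted p = 0.0165 with an estimated correlation). ccg-4, a pheromone precursor gene of mat A strains, had 1079 reads against none in WT, matA-1 stood at 34.9 CPM ± 6.65 against 0.534 ± 0.123 (SD, n = 3), and asd-1, pre-1 and per-1 were 2.21-fold, 1.79-fold and 1.43-fold higher. No other mutant group had more than 3 matA-1 reads, and ccg-4 averaged at most 0.357 CPM in the other groups of series 118. The rise of ccg-4 and matA-1 thus cannot be told from a difference in strain or mating type. The list call rests partly on both genes and was not tested without them. NCU07091 had 5065 reads against 2 (ratio 2220, counting interval 614 to 18300), NCU12069 4048 against 2 (1770, 491 to 14700), and NCU09604 and NCU08969 were 193-fold and 125-fold higher. NCU04496, at 289 TPM ± 19.8 in WT (SD, n = 3), was 23.1-fold lower, and NCU01678 and NCU07581 were 14.2-fold and 13-fold lower. NCU09968 had 6 reads against 3278, at 0.135 CPM ± 0.157 against 81.7 ± 2.26 (SD, n = 3). Light genes fell, 6 of 11 (camera adjusted p = 0.0081; adjusted p = 0.376 with an estimated correlation). Glycoside hydrolases had 24 of 75 higher and 4 lower (0.0247), the peroxisome 6 of 20 lower (0.0103), complex I 4 of 29 lower (0.0237) and the proteasome 3 of 17 lower and 1 higher (0.0348), each with adjusted p = 0.566 with an estimated correlation. In total 2951 of 9339 genes changed (limma), 1657 higher and 1294 lower.

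Glycoside hydrolases rose in the libraries labelled acf iaf-2, 35 of 75 with 1 lower (camera adjusted p = 2.17e-05; adjusted p = 0.468 with an estimated correlation), as did the cellulose list, 4 of 10 and 5 adjusted over the list alone (0.0275; adjusted p = 0.316 with an estimated correlation). Light genes fell, 6 of 11 with 1 higher and 8 adjusted over the list alone (0.00918; adjusted p = 0.316 with an estimated correlation), and complex I had 4 of 29 lower (0.00792; adjusted p = 0.468 with an estimated correlation). NCU07091 had 4530 reads against 2 (ratio 1890, counting interval 523 to 15600), NCU06953 1061 against 3 (295, 101 to 1430), NCU08796 had 3027 against 9, and NCU09604 was 149-fold higher. NCU00995 and NCU05068 were 91.3-fold and 7.81-fold lower, and NCU09968 and NCU09969 at least 1310-fold and 193-fold lower. In total 2306 of 9339 genes changed (limma), 1824 higher and 482 lower, a higher share of 79.1% that was 66.3% with median-ratio scaling.

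In the iaf-1 iaf-2 double mutant, with 2 libraries, complex I genes fell, 14 of 29 (camera adjusted p = 8.16e-07; adjusted p = 0.11 with an estimated correlation). Light genes also fell, 4 of 11 and 6 adjusted over the list alone (0.00778; adjusted p = 0.29 with an estimated correlation). Amino acid synthesis had 7 of 53 lower and 1 higher (0.0164; adjusted p = 0.789 with an estimated correlation), and the ISWI complex list, which holds the deleted genes, had 2 of 4 lower (0.00212; adjusted p = 0.248 with an estimated correlation). NCU16805 stood at 240 TPM ± 50.4 (SD, n = 2) against 2.01 ± 0.788 (SD, n = 3), 81.1-fold higher, and NCU08969 was 49.8-fold higher. NCU09339 had 700 reads against 2 (386, counting interval 106 to 3190), and NCU01943 was at least 112-fold higher. mig-4, NCU07088 and NCU06170 were 13-fold, 11.9-fold and 8.71-fold lower, and eas was 9.34-fold lower, a call lost without replicate 2 of the mutant (log2 fold change -2.15). In total 2007 of 9339 genes changed (limma), 1307 higher and 700 lower, and 994 did with only the compared groups in the fit.

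The study's title asks whether ISWI is needed for repression in PRC2 target domains, and the 263 genes higher at least 2-fold in set-7 were followed in mutants with other WT libraries. This list was chosen on the series 112 samples and is no independent evidence of PRC2 targets. In isw, 167 of 255 tested list genes rose and 34 fell (169 and 38 adjusted over the list alone), with a median log2 fold change of 1.40, while 28% of other genes rose (camera adjusted p = 4.27e-14; adjusted p = 7.80e-05 with an estimated correlation). In the libraries labelled acf iaf-1, 153 rose and 14 fell (median 1.08, adjusted p = 4.88e-28), in those labelled acf iaf-2, 170 and 10 (1.20, 1.94e-27), in the triple mutant of series 118, 173 and 27 (1.52, 6.91e-16), and in iaf-1 iaf-2, 87 and 7 (0.34, 1.21e-07). With genes that had no read in a group at their bound, the median was 1.47 in isw and 1.31 in acf iaf-2, lay 0.06 above the fitted one in acf iaf-1 and did not move in the other mutants at this precision. The filter for low values left 181 of the 263 list genes in series 111 and 255 in series 118, so shares and medians of these series cover different genes. Their scales differ too, with edgeR on counts in series 111 and limma on log2(TPM + 1) in series 118. In the libraries labelled acf of series 111, 106 of 181 rose and 24 fell (median 1.41, camera adjusted p = 6.40e-09). With close pairs summed 104 of 194 rose and 20 fell (camera adjusted p = 1.23e-09). In iaf-1, 34 rose and 16 fell (median 0.18, camera adjusted p = 0.107), and in iaf-2, 22 and 9 (0.04, 0.191). The fry test, which asks only whether the list moves on balance one way, called both (fry adjusted p = 0.00012 and 0.00625). It was run only with the near-identical libraries counted as separate samples. With close pairs summed 20 rose and 3 fell in iaf-1 (camera adjusted p = 0.085), and the 4 genes then called in iaf-2 were not on the list (0.157). Whether the list moved differently in iaf-1 or iaf-2 than in other mutants was not tested. Of 255 list genes tested in both comparisons, 150 were higher at least 2-fold in isw, against 33.72 for independent lists (Fisher's exact odds ratio 10.62, interval 8.148 to 13.89). With no fold minimum 266 were higher in both, against 179.9 (odds ratio 1.919, 1.621 to 2.269).

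**Figure D2:**
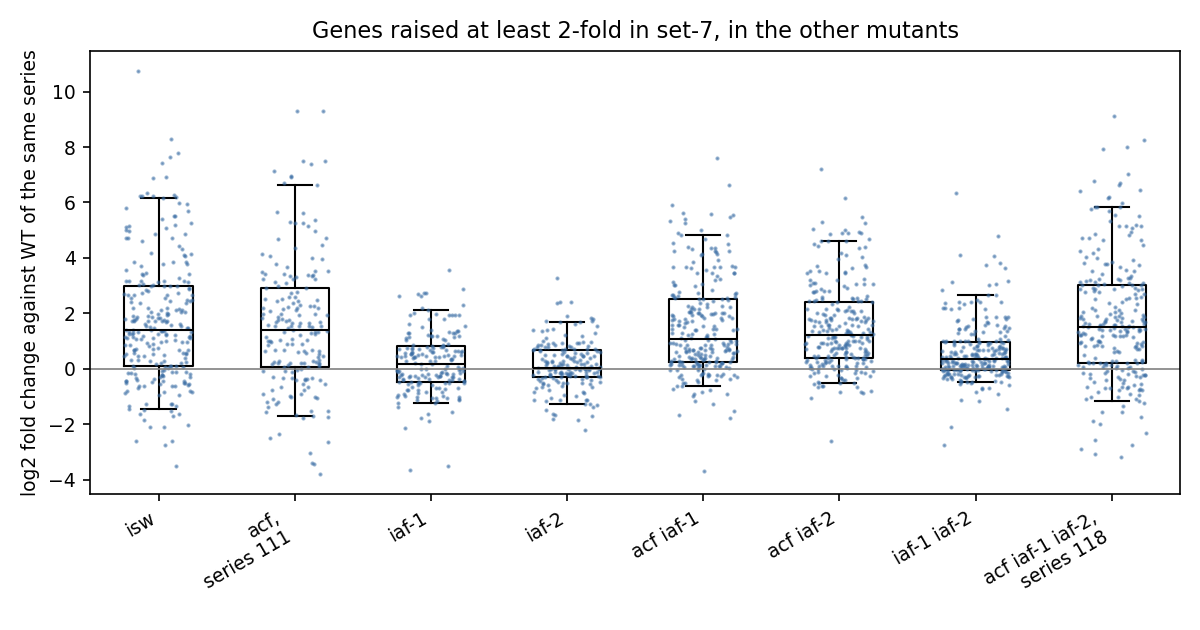
Log2 fold change against WT (vertical axis) of the genes higher in set-7, as points per mutant (horizontal axis), with boxes at the quartiles and whiskers from the 5th to the 95th percentile. Points cover 181 genes in the mutants of series 111 and 255 in those of series 118. The medians run from 0.04 in iaf-2 to 1.52 in the triple mutant of series 118.

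Genes raised in the libraries labelled set-7 gathered at chromosome ends. Of 249 genes with a position, 87 (34.9%) were among the 50 genes nearest an end, where 6.96% of tested genes lay (Fisher's exact odds ratio 8.23, 6.17 to 10.9; rotation permutation p = 0.0067). In the libraries labelled acf 86 of 582 genes were at ends (odds ratio 2.63, 2.03 to 3.38, and 2.37 with close pairs summed; rotation p = 0.0108, a permutation test), and in the triple mutant 119 of 1184 (10.1%, 1.62, 1.3 to 2; rotation permutation p = 0.0461). With 25 genes per end the odds ratio of the triple mutant was 1.26 and no longer passed Fisher's exact test (p = 0.149). In isw 124 of 1304 were at ends (9.51%, 1.49, 1.2 to 1.84), which did not pass the rotation permutation test (p = 0.0639), nor Fisher's exact test with 25 genes per end (1.24, p = 0.168) or with no fold minimum (1.01, p = 0.964). Among the 10 outermost genes of each end, 38.2% were raised in set-7, 21.8% in isw, 21.2% in acf and 17.1% in the triple mutant, and beyond gene 100 these shares were 1.3%, 13.2%, 6% and 12%. In isw and acf the highest share was not at the very end but among genes 51 to 60, at 29.3% and 23.8%, and in the triple mutant it was 26.4% among genes 81 to 90. In set-7 the share was 3.7% among genes 41 to 50 but 16.1% among genes 51 to 60. The shares were not tested against each other.

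**Figure D3:**
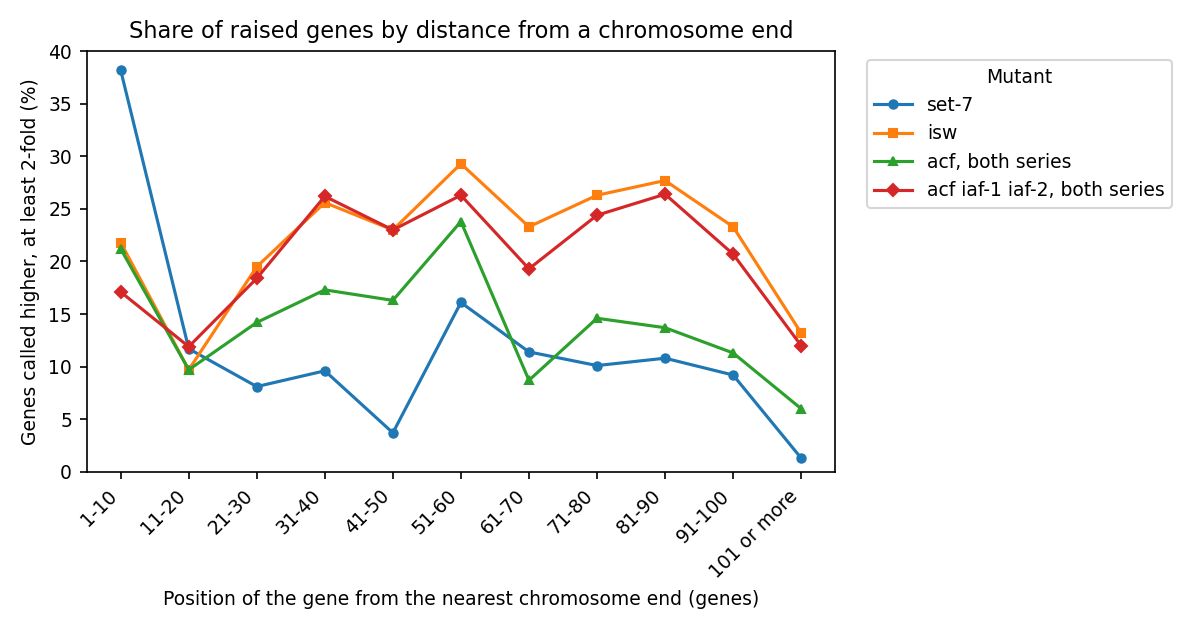
Percent of tested genes called higher at least 2-fold (vertical axis) by distance from the nearest chromosome end in bins of 10 genes (horizontal axis), with a line per mutant. The set-7 line starts at 38.2% in the first bin, is at 3.7% for genes 41 to 50 and 16.1% for genes 51 to 60, and ends at 1.3% beyond gene 100. The isw line starts at 21.8%, peaks at 29.3% for genes 51 to 60 and ends at 13.2%.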

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

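The genotype by series interactions, median-ratio scaling and counts over other splits of unsummed libraries were planned. All other tests in this part were chosen only after the result was seen. The effect in the libraries labelled acf differed between series 111 and 112: the genotype by series interaction called 3920 of 8252 genes (edgeR). WT libraries of series 111 that stand apart would move iaf-1 and iaf-2, set against the same WT, along the difference; over 3888 genes their medians along it were 0.32 and 0.18 log2 units (upper quartile 0.61 in iaf-1) against 1.19 for acf (0.39 and 0.24 against 1.32 over 3485 genes with close pairs summed), which argues against this as the whole source. Counting near-identical libraries as separate samples was also argued against, with 3513 genes left after each close pair was summed. An exchange of acf libraries with another mutant of series 111 was argued against as well, since 67.6% of 413 genes raised in acf of series 112 were higher in acf of series 111, against 19.4% in iaf-1 and 9.9% in iaf-2 (64.1%, 9.1% and 0% of 451 genes with close pairs summed). Different acf isolates or a different state of the cultures stay open and were not tested. The acf libraries of series 111 carry pass0 in their labels, without a stated meaning, and those of series 112 do not.

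Genes lower in the libraries labelled set-7 gathered on chromosome I, in the region of the mating-type locus. Of 69 genes lower at least 2-fold, 12 lay within 150 genes of matA-1, a window chosen once they were seen, where 2.17 would lie by their share. Of these 12, 7 lay -113 to -64 genes from matA-1. An even spread along the genome was argued against by shuffles that looked for the fullest window anywhere. matA-1 was left out and lower genes within 5 genes of the last one were merged (permutation p = 0.0068 over 5 window sizes, though 0.1 at 50 genes on each side). The fullest windows, the first where several tied, were centred -214 to -89 genes from matA-1. Those of 25 to 150 genes on each side did not reach matA-1, so the shuffles show a cluster on chromosome I but not one at the locus itself. A strain segment that set-7 shares with iaf-1, and perhaps with acf of both series, may account for the gathered lower genes. The window genes were also lower in iaf-1, with a median log2 fold change of -1.02 against 0.28 for the other lower genes (permutation p = 0.0166). With close pairs summed these were -1.01 against 0.44 (permutation p = 0.0076). The permutation treats genes as independent, which neighbours on a shared segment are not, and its window genes include matA-1. It gave permutation p = 0.0081 in acf of series 111 and 0.017 in iaf-2 (0.0081 and 0.0328 with close pairs summed). In acf of series 112 it gave 0.0217, and in the remaining mutants other than set-7 0.156 or above. That iaf-1 kept its set-7 gene rests on the label, though. Its set-7 reads stood at 3.77 CPM ± 0.411 against 8.19 ± 4.57 in WT (SD, n = 3, edgeR adjusted p = 0.0547). WT replicate 2, at 2.925 CPM, lay below every iaf-1 library. Medians of window and other lower genes were -0.52 and 1.45 in acf of series 111 and -0.12 and 0.34 in iaf-2, with the same WT as iaf-1, -1.16 and -0.75 in acf and -0.64 and -1.07 in the triple mutant of series 112, with the same WT as set-7, -0.18 and 0.02 in isw, 0.52 and -0.15 in acf iaf-1 and 0.28 and 0.18 in the triple mutant of series 118. They were 0.26 and 0.23 in acf iaf-2 and 0.44 and 0.37 in iaf-1 iaf-2, which had no matA-1 read, so the segment would not go with the mating type in every strain, and a role of PRC2 at these genes stays open.

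mfa-1, pre-2 and per-1 were high in isw and in the triple mutant of both series. The mating type of the strains alone was argued against, since in 20 libraries of 7 other groups with at most 2 matA-1 reads the highest mfa-1 level was 79.5 CPM, against a lowest of 5090 in isw and the triple mutant. RNA of sexual structures could not be judged: the highest log2 fold change of the other sexual development genes was 0.38 in isw and 0.41 in the triple mutant of series 118, where 4 were tested, but 1.12 in the triple mutant of series 112, where 2 of 3 were called higher with a median of 0.95. A loss of repression at these genes in the mutants stays open as a hypothesis.

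The effect of the triple mutation differed between series 112 and 118 at 2231 of 9294 genes (limma interaction). Of these 72.7% had the higher fold change in series 118, and 50.3% with median-ratio scaling, which moved the median of all genes from 0.186 to -0.009.

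For each comparison of 3 libraries with 3, 10 splits exist, too few for a share under 0.05, and the real one was the 1 with the highest value. Real and highest other counts of changed genes were 1235 and 0 for set-7, 4513 and 1 for isw, 5265 and 0 for acf of series 111, 2381 and 0 for acf of series 112, 2299 and 320 for iaf-1 and 1564 and 3 for iaf-2. They were 2951 and 1 for acf iaf-1, 2306 and 1 for acf iaf-2, 4805 and 0 for the triple mutant in series 112, 4768 and 0 in series 118, 4214 and 0 against acf and 1634 and 1 against isw. Of the set-7 list, real and highest other counts of higher genes were 167 and 0 in isw, 106 and 0 in acf of series 111, 34 and 3 in iaf-1, 22 and 0 in iaf-2, 153 and 0 in acf iaf-1, 170 and 0 in acf iaf-2 and 173 and 0 in the triple mutant. Over both series, 100 splits were drawn, and only the real one reached 2404 genes for acf (highest other 2) and 5008 for the triple mutant (highest other 1361). With close pairs summed and moved as 1 sample, only the real one of 60 splits reached 1111 for acf (highest other 263). A chance split of these libraries is thus an unlikely source of either count, as far as 100 splits can show. This does not show that libraries came from separate cultures. For the interactions 1 split reached 3920 (highest other 3379), or 2 of 60 reached 3513 with close pairs summed (highest other 3943), and 2 reached 2231 (highest other 2609). Such splits exchange libraries within 1 series and leave the other's whole effect as a difference, a structure of the samples. The iaf-1 iaf-2 mutant, with 2 libraries, was not split.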

How the results depend on the processing

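Summed close pairs, edgeR on recovered reads and other pseudocounts were chosen after seeing the data; other alternatives were planned. Of 371 alternatives over 30 results, 349 kept the direction and the side of the threshold, or a count within 1.5 times, and 0 reversed a direction. For counts this label covers the total only, and the majority of higher or lower genes turned in some settings, of which the results give some. With only the compared groups in the fit, 447 genes changed in set-7 in place of 1235, 792 in iaf-2 in place of 1564 and 994 in iaf-1 iaf-2 in place of 2007; these fits rest on fewer libraries. With each close pair summed, 1111 changed in acf over both series in place of 2404, 476 in iaf-1 in place of 2299 and 4 in iaf-2, where fewer samples stand behind each group. With 1 library left out, counts ran from 741 (without WT replicate 2) to 1585 in set-7, from 1592 (without WT replicate 3 of series 111) to 2592 in acf over both series, and from 846 (without isw replicate 1) to 1544 in the triple mutant against isw, where 951, 985 and 1056 came without triple mutant replicate 2, isw replicate 2 or isw replicate 3. In iaf-2 they ran from 769 (without iaf-2 replicate 3) to 2759 (without WT replicate 2), with 790 and 871 without WT replicate 1 or 3 and 912 and 951 without iaf-2 replicate 1 or 2. Leaving out 1 library of iaf-1 iaf-2 leaves a lone sample, assumed to vary like the other groups. The odds ratio of raised genes at chromosome ends was 1.24 in isw and 1.26 in the triple mutant with 25 genes per end, and 1.01 in isw with no fold minimum, none past Fisher's exact test; the cause was not tested.

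The labels' replicate numbers did not pair the samples: in no comparison did all same-numbered libraries correlate above 0.1 in their deviations. In iaf-2, where every library correlated best with its own number, the correlations ran from 0.043 to 0.105. With the replicate block, 978 genes changed in acf over both series, 600 higher and 378 lower, a higher share of 61.3%. No other of 26 results was altered, nor any of 255 list results. Of the named genes 208 were still called and 14 were not: set-7 in set-7, sub-1 in isw, pre-1 in the triple mutant and, in acf over both series, NCU02238, NCU09388, hpo, dim-2, hH2A, con-6, cry, clr-1, cbh-1, hsp30 and hsp88. Of 3047 alternatives for named genes 2940 left the call in place. Leaving out 1 library ended a call in 69 of 1832 cases. Estimated correlation ended 49 list calls. Depth limited genes with few reads, whose folds are given as bounds or with counting intervals.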

Other observations

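The gene counts and values in this part were looked at after the data had been seen, and no explanation was tested here. Genes higher at least 2-fold in the libraries labelled acf of series 112 were followed in series 118, which has other WT libraries. Of 641 such genes tested there, 560 (87.4%) were higher in acf iaf-1 (limma), where 12.6% of other genes were, and 581 (90.6%) in acf iaf-2, where 14.3% were. In isw 564 (88%) were higher, beside 24.6% of other genes, and in the triple mutant 572 (89.2%), beside 25.4%. In iaf-1 iaf-2, which carries no acf deletion per the labels, 322 (50.2%) were higher, beside 11.3%. Whether these shares differ between mutants was not tested.

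Reads of NCU09968 and matA-1 varied between groups in a way that crossed the genotypes. NCU09968 averaged 119 CPM, 90.8 CPM and 81.7 CPM in WT of series 111, 112 and 118. It stood at 59.5 CPM in iaf-2, 41.5 CPM in isw and 39 CPM in iaf-1 iaf-2, had 2 reads in iaf-1 and 6 in acf iaf-1, and none in set-7, in acf of either series, in acf iaf-2 or in the triple mutant of series 118. In the triple mutant of series 112 it had 48 reads, of which 1 library held 42. matA-1 averaged 17.4 CPM ± 3.39, 1.81 ± 1.34 and 0.534 ± 0.123 (SD, n = 3) in WT of the 3 series and 34.9 ± 6.65 in acf iaf-1, and the other groups had at most 3 reads each. Low or high matA-1 in a mutant therefore cannot be told from a difference in strain or mating type between that mutant and WT. Nor can a loss of NCU09968 or its neighbour NCU09969 be told from a difference in strain.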
